A study of Macrocystis pyrifera with 6 samples.

How the data were processed

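Messenger RNA was sequenced from immature gametophytes of the giant kelp Macrocystis pyrifera, the haploid stage of the life cycle on which sex is expressed in kelps. There were 3 strains with 2 libraries each. The wild-type female libraries came from strain Cur4F, the wild-type male libraries from strain Cur6M, and the third group was the line Mpyr-13-4, strain Cur6M-Colch-13-4, whose phenotype the labels give as partial sex reversal and whose sex they give as female. Its treatment label reads 1 mg colchicine for 12 to 16 weeks, without a volume. Colchicine is an alkaloid that blocks microtubule assembly. Per the labels' protocols, gametophytes grew in enriched sea water at 13 °C under red light on a cycle of 14 h day and 10 h night, each library came from a separate bulk of about 1000 individuals, cDNA was primed with oligo-dT, and reads were 150 bp and single-end. The libraries of a strain are therefore separate bulks of the same strain, and p-values measure the spread between such bulks. Sex and strain cannot be told apart in the comparison of female with male.

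The read counts per gene were made by the authors with featureCounts 1.6.3 from alignments by TopHat2, per the file headers, over exons grouped by gene. The counting command names no strand option and no option for reads that overlap several genes or map to several places. Reads from a gene and an overlapping or antisense model cannot be told apart in such counts, and models that overlap are reported as uncertain. The submitters' processing notes also list FastQC, Trimmomatic, Bowtie2, DESeq2 and deepTools 3.2.0. The genome build is not given in the sources used here, and coordinates are those of the contigs in the authors' annotation. The count table held 22242 genes on 15881 contigs with their summed exon length, and every sample column was matched to a sample by its name. The authors' deposited tables of the 3 comparisons hold log2 fold changes with standard errors, a score (the Wald statistic), p-values and adjusted p-values, per the file headers. They also hold a signal per library, the authors' deposited counts divided by a size factor, and its mean. The fold changes of a DESeq2 fit made here on the deposited counts differed from those of the authors' deposited tables by at most 9.70e-05 on the log2 scale for every gene the authors' tables call.

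Total counts per library were 19752949 and 32143954 in female, 26874089 and 25524084 in male, and 14129889 and 21413894 in the variant. At these depths 3 reads correspond to between 0.0954 and 0.236 CPM, read counts scaled by library size, which is the upper limit that 0 reads allow in a single library. Over both libraries of a group the limit is 0.0616 CPM in female and 0.0489 CPM in male. The 10 most abundant genes took between 7.40% and 8.75% of the reads of each library. Intervals and limits cover counting error only. CPM were computed on library sizes scaled by TMM.

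Counts were tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F-test, robust dispersions, TMM scaling and the tool's default expression filter, which left 15905 genes. All 6 libraries entered a single fit with a mean per group, so that the third group added to the estimate of spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a second count required a fold change of at least 2. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so single values carry no such test. Sex-biased genes were those called between female and male with at least a 2-fold difference. The position of the variant on such a gene was the difference of the variant from male divided by the difference of female from male in log2 CPM (prior count 2), so that 0 is the male level and 1 the female level. Sex-limited genes had at least 1 CPM in both libraries of a sex and at most 0.1 CPM in both libraries of the other. Variant-specific genes differed by at least 2-fold, in the same direction, from both sexes. Chance agreement between comparisons that share control libraries was taken from 20 simulated data sets without effects, and shared calls from a further 5. Neighbouring genes were compared with 10000 random placements of the same number of genes. Steps were tested on simulated counts with 200 changed genes. In the simulated comparison of female with male, over 15634 genes, 100% of 8-fold changes, 98% of 4-fold, 48% of 2-fold and 6% of 1.5-fold changes were called, and 8.03% of all calls were false. In that of the variant with female, over 15621 genes, 94%, 92%, 42% and 16% were called, with 8.96% false calls. In that of the variant with male, over 15639 genes, these shares were 92%, 92%, 40% and 6%, with 3.36% false calls. Far more than 200 genes were called in each comparison of the data, and the adjustment depends on how many genes change. These shares therefore need not hold for the data. Figures were drawn with matplotlib 3.10.9.

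The files do not pair gene IDs with names and no annotation of products was used here, so the lists of product names fixed for flagella, ribosomal proteins, photosynthesis, cell cycle, meiosis, chromatin, cell wall, oxidative stress, chaperones, microtubules, lipids, translation, transposable elements and bacterial products were not run. Genes were named by a fixed rule: per comparison the 2 genes highest and the 2 lowest in fold change among those called with at least 10 CPM in both libraries of the higher group and no overlap between groups, the 2 sex-limited genes of highest CPM per sex, and the largest change on each side among sex-biased and variant-specific genes. Gene models whose IDs carry SDR, HMG or MSTRG were chosen after the table had been seen, and so were the members named from them. SDR is the usual abbreviation of sex-determining region in organisms with U and V sex chromosomes, in which females carry a U and males a V, and HMG that of a high mobility group domain. The files do not spell either out. MSTRG is the default prefix of the transcript assembler StringTie. Models that share exons were also summed to loci. Overlap was looked for only among these models, so a model said to have no overlap may still overlap another gene of the annotation.

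Alternatives were another scaling, 2 other filters, DESeq2 1.42.0, the authors' deposited tables, the replicate number as a block, the series of the sample codes as a term, each library left out, fits with only the groups compared, and other thresholds for biased and limited genes. The sample codes fall into the 150s (female replicate 1 and both variant libraries) and the 170s (female replicate 2 and both male libraries). The labels do not say what the codes stand for. Design, groups, tests, alternatives and the rule for named genes were chosen before the data were examined, apart from what is said to have been added.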

Results

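The data were read counts per gene from 6 libraries of giant kelp gametophytes, 2 each of a wild-type female strain, a wild-type male strain and the line Mpyr-13-4, called the variant here. Its strain name carries that of the male strain, from which its derivation is read, and it is described as partially sex-reversed. Library totals ranged from 14129889 reads in variant replicate 1 to 32143954 in female replicate 2. Of 22242 genes, 19208 had a read in some library and 15905 were tested. Counts within each pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.57 in female, 52.7 in male and 20.1 in the variant, so no pair was a duplicate deposit.

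The libraries of the variant lay near those of female and far from those of male. The Euclidean distance in log2 CPM averaged 134 between variant and female libraries (4 pairs, range 130 to 138), 232 between variant and male libraries (4 pairs, 219 to 249) and 242 between female and male libraries (4 pairs, 226 to 257). Replicates of a group lay 42.1 apart in female, 65.5 in male and 65.2 in the variant. The Spearman correlation across genes was 0.950 to 0.957 for variant with female and 0.820 to 0.873 for variant with male. The first principal component held 76.2% of the variance and parted male from the other groups. The second held 18.4% and parted the variant from female.

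**Figure D1:**
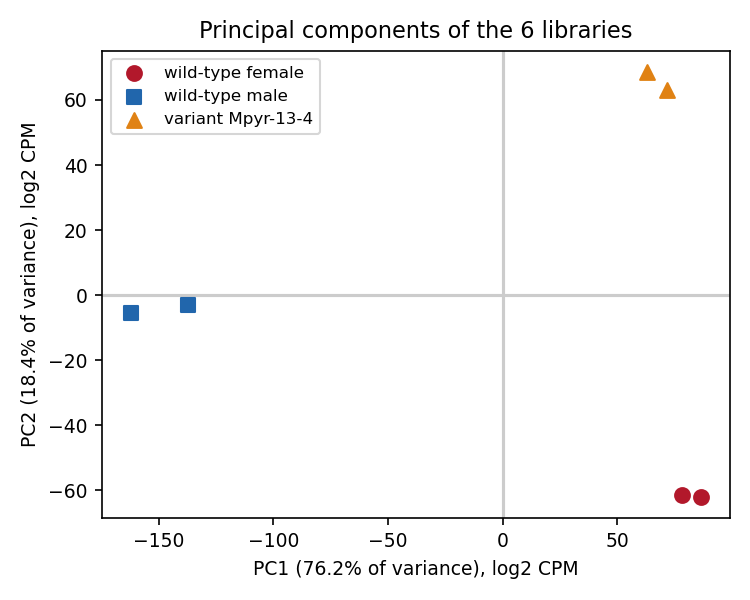
Each point is a library, placed by its first 2 principal components of log2 CPM over the 15905 tested genes, with the share of variance on each axis. The male libraries lie at -137 and -162 on the first axis, the female libraries at 86.6 and 78.0 and the variant libraries at 62.7 and 71.7, while the second axis sets the variant (68.6 and 63.2) apart from female (-61.9 and -61.3).

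The comparison of wild-type female with wild-type male asked which genes differ between the sexes at the immature stage, in strains that also differ in origin. The 2 genes with the highest fold in female were g259 on contig jcf7180004593899 (6231 to 15613, 14 exons) and g55913 on contig jcf7180004793358 (11782 to 17724, 3 exons). g259 was at 69.4 CPM ± 2.83 (SD, n = 2) in female with 0 reads in male, at least 1421-fold higher against the limit of 3 reads over the group, and g55913 was at 39.6 CPM ± 0.893 (SD, n = 2), at least 811-fold higher. In male the corresponding genes were g27376 on contig jcf7180004726408 (10831 to 12769, 2 exons), at 31.2 CPM ± 4.38 (SD, n = 2), and g24085 on contig jcf7180004724516 (8593 to 12250, 4 exons), at 20.1 CPM ± 1.54 (SD, n = 2). Both had 0 reads in female and were at least 507-fold and 326-fold higher in male. Expression differed between the sexes at 9129 genes, of which 4635 were higher in female and 4494 higher in male (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). With at least a 2-fold difference there were 2648 genes biased to female and 3000 biased to male, together 35.5% of the genes tested. Differences of at least 16-fold were called at 781 genes higher in female and 610 higher in male. The authors' deposited table calls 8616 genes at the same threshold, and 8404 genes were called by both, none in opposite directions. Female replicate 2 shares its series of sample codes with the male libraries. With that female library alone 6158 genes were called, and with female replicate 1 alone 5896.

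Some genes were expressed in a sex and at or near 0 reads in the other. At the thresholds of 1 and 0.1 CPM, 365 genes were limited to female and 191 to male. The most abundant female-limited genes were g72788 on contig jcf7180004817596 (62 to 6291, 7 exons), at 276 CPM ± 8.41 (SD, n = 2) in female, and g76626 on contig jcf7180004820433 (1430 to 3365, 3 exons), at 111 CPM ± 3.73 (SD, n = 2). They had 5 and 4 reads in the male libraries together, ratios of 3367 (95% counting interval 1442 to 10370) and 1716 (670 to 6300). The most abundant male-limited genes were g76937 on contig jcf7180004820673 (219 to 1199, 1 exon), at 123 CPM ± 14.8 (SD, n = 2) in male, and g74292 on contig jcf7180004818568 (4556 to 8977, 3 exons), at 116 CPM ± 7.49 (SD, n = 2). Each had 3 reads in the female libraries, ratios of 1994 (682 to 9674) and 1879 (643 to 9113). Sex and strain differ together in these genes, since each sex was represented by 1 strain.

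The comparison of the variant with wild-type male set the line against the strain it came from, as read from its strain name. The genes with the highest fold in the variant were g75683 on contig jcf7180004819601 (27203 to 44600, 9 exons), at 68.8 CPM ± 10.3 (SD, n = 2), and g67875 on contig jcf7180004811629 (220 to 20148, 18 exons), at 66.7 CPM ± 10.5 (SD, n = 2). Both had 0 reads in male, at least 1407-fold and 1364-fold lower than in the variant, and both were read in female, at 16.4 CPM ± 1.07 and 8.14 CPM ± 5.39 (SD, n = 2). g75683 was also the female-biased gene with the largest rise over male in the variant. The genes with the lowest fold were g44297 on contig jcf7180004748942 (2481 to 5661, 2 exons) and g79778 on contig jcf7180004823387 (10946 to 28403, 2 exons). g44297 had 0 reads in the variant against 215 CPM ± 27.4 (SD, n = 2) in male, at least 2323-fold lower. g79778 had 2 reads in the variant against 127 CPM ± 13.1 (SD, n = 2) in male, a ratio of 2060 (95% counting interval 570 to 17011), and was the male-biased gene with the largest fall. It was at 0.164 CPM ± 0.00232 (SD, n = 2) in female. The variant differed from male at 8001 genes, 4216 higher and 3785 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), and at 4868 of them by at least 2-fold, 2271 higher and 2597 lower. The authors' deposited table calls 7564 genes, of which 7342 were called here too, none in opposite directions. No variant library shares a series of sample codes with a male library, so no comparison within a series could be made. With the series as a term 1847 genes were called, while the standard errors grew by a median factor of 2.05 and the fold changes of the called genes had a median ratio of 0.985 to those without the term. Of the 8001 genes, 60 took the opposite sign under that term.

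The comparison of the variant with wild-type female asked what still sets the variant apart from a female. The genes with the highest fold in the variant were g27376, at 53.1 CPM ± 12.2 (SD, n = 2) and at least 862-fold higher than in female, and g47218 on contig jcf7180004752565 (3517 to 19212, 25 exons), at 26.8 CPM ± 3.98 (SD, n = 2) and at least 435-fold higher. g27376 was also expressed in male, as given above, and g47218 was at 0.472 CPM ± 0.0524 (SD, n = 2) in male. The genes with the lowest fold were g44297, at 253 CPM ± 2.03 (SD, n = 2) in female, and g38514 on contig jcf7180004740659 (3495 to 8393, 5 exons), at 191 CPM ± 5.07 (SD, n = 2) in female and 0.146 CPM ± 0.0178 (SD, n = 2) in male. Both had 0 reads in the variant, at least 2728-fold and 2066-fold lower than in female. The variant differed from female at 1953 genes, 1140 higher and 813 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), and at 1224 by at least 2-fold, 650 higher and 574 lower. The authors' deposited table calls 2213 genes, of which 1863 were called here too, none in opposite directions. This count moved most with the libraries used. It was 441 against female replicate 1, which shares the variant's series of sample codes, 585 against female replicate 2, 464 with the series as a term, 873 without variant replicate 1, 980 without variant replicate 2, 3322 and 3321 without male replicate 1 or 2, and 3326 in a fit without the male libraries.

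Most sex-biased genes had shifted in the variant from the male toward the female level. Of the 2648 female-biased genes, 2200 (83.1%) were higher in the variant than in male, and 1762 of these were not called against female. A further 220 lay between the sexes and 218 lay above female. Of the 3000 male-biased genes, 2422 (80.7%) were lower in the variant than in male, 2124 of them with no call against female, 211 between the sexes and 87 below female. At 192 female-biased genes (7.25%) and 194 male-biased genes (6.47%) the variant was called against female and not against male. The variant was called away from female at 20 and 46 genes, and 236 and 338 were not called against either sex. No call against female does not place a gene at the female level, since only 42% of simulated 2-fold changes between variant and female were called. The number of calls in that comparison also moved with the libraries used, as given above. The median position of the variant, with male at 0 and female at 1, was 0.849 on female-biased genes (0.824 and 0.901 in the replicates, SD 0.0543, n = 2) and 0.881 on male-biased genes (0.855 and 0.905, SD 0.0352, n = 2). When a group was simulated with the male means, the positions were 2.51e-05 and 0.0175, and with the female means 0.986 and 0.992. Among genes with at least a 4-fold sex bias the positions were 0.958 and 0.950. With the series of sample codes as a term 1128 female-biased and 524 male-biased genes were called toward female. Positions on the genes biased under that term were 0.857 and 0.865. They were measured on log2 CPM from which the term was not removed, so they cannot show whether the series moved the position.

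**Figure D2:**
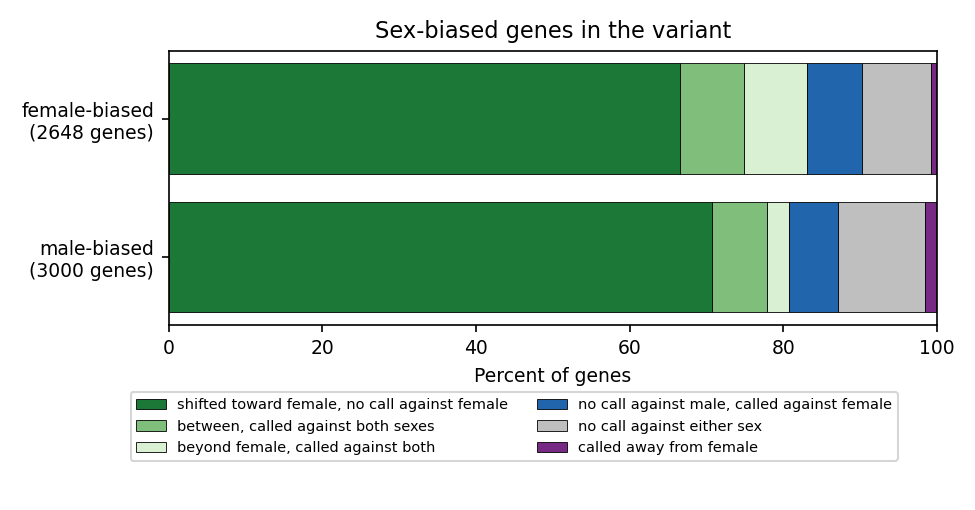
Bars show the percent of female-biased and of male-biased genes in each class of the variant, from its calls against male and against female. In 66.5% of female-biased and 70.8% of male-biased genes the variant had shifted toward female with no call against female, while 7.25% and 6.47% were called against female and not against male. No call does not show that the levels were equal.

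Fold changes of female over male and of the variant over male were correlated across genes with r = 0.850, where simulated groups without effects that shared the male libraries gave 0.462. The covariance was 2.91 against 0.0467 in the simulation. Higher in both were 3489 genes and lower in both 3175, against 1229 and 1069 for independent lists of the same sizes. The averages were 0 and 0.2 in 5 simulated sets. At most 1 gene per comparison was called there, so this overlap was bound to be near 0. For male and the variant, each over female, r was 0.352 against 0.492 simulated, the covariance 0.679 against 0.0506, and 615 and 532 genes were higher or lower in both, against 322 and 237 for independent lists. The simulation gave all groups the same spread for a gene, while replicates lay 42.1 apart in female, 65.5 in male and 65.2 in the variant. The simulated r is therefore not exact for either shared group. An r below it, beside a covariance above it, does not show agreement below chance. The observed values were not computed with the control libraries split, so part of the excess may come from the shared libraries. A split by replicate was made for the position of the variant alone and is given below. Genes are not independent replicates.

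Sex-limited genes of either sex were found on in the variant. Of the 365 female-limited genes, 247 (67.7%) had at least 1 CPM in both variant libraries, 47 had at most 0.1 CPM in both, and 41 had 0 reads. Of the 191 male-limited genes, 65 (34.0%) were on, 43 were off and 20 had 0 reads. In the variant g72788 was at 119 CPM ± 28.7 (SD, n = 2) and g76626 had 0 reads, while g76937 was at 103 CPM ± 20.1 (SD, n = 2) and g74292 at 251 CPM ± 27.1 (SD, n = 2). The share on was higher for female-limited than for male-limited genes, with an odds ratio of 4.05 (95% interval 2.75 to 5.99, two-sided Fisher's exact test across genes, p = 3.96e-14), a test added after the counts had been seen. With at least 5 CPM asked of the expressing sex, 85 of 137 female-limited and 31 of 59 male-limited genes were on and the odds ratio was 1.47 (0.759 to 2.86, Fisher's exact p = 0.267). With 0 reads asked of the other sex it was 1.90 (1.06 to 3.45, Fisher's exact p = 0.0259).

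Outside the range of the sexes, 306 genes were at least 2-fold higher and 211 at least 2-fold lower in the variant than in both. Of the higher genes, 165 were female-biased, 34 male-biased and 107 neither. Of the lower genes, 18 were female-biased, 77 male-biased and 116 neither. The largest rise was at g74321 on contig jcf7180004818581 (11227 to 22233, 3 exons), at 62.1 CPM ± 4.43 in the variant, 0.398 CPM ± 0.0484 in female and 0.410 CPM ± 0.130 in male (SD, n = 2 each). Its log2 fold change was 7.23 (SE 0.226, edgeR adjusted p = 1.12e-06) against male and 7.29 (SE 0.234, edgeR adjusted p = 7.27e-06) against female. The largest fall was at g44297. With the series of sample codes as a term the counts were 62 and 39, and without female replicate 2 they were 101 and 55.

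The annotation holds 57 gene models on 4 contigs whose IDs carry SDR (22 models), HMG (1) or MSTRG (34), which fall into 20 loci once models that share exons are joined. gSDR.13001910 (contig jcf7180004741608, 6508 to 124399, 15 exons, no overlapping model of the set) was at 91.7 CPM ± 14.2 in male, 88.9 CPM ± 23.2 in the variant and 0.0828 CPM ± 0.117 in female (SD, n = 2 each). Its log2 fold change between variant and male was -0.05 (SE 0.243, edgeR adjusted p = 0.889), and 4.97 (adjusted p = 0.227) with the series of sample codes as a term, which for this model rests on 0 and 5 reads in the female libraries. gSDR.13001840 (contig Mp_4794405_Mp_4806178, 1 to 9083, 2 exons) was at 18.4 CPM ± 10.0 in male, 3.39 CPM ± 0.0118 in the variant and 0.0497 CPM ± 0.0702 in female (SD, n = 2 each), with a log2 fold change of the variant against male of -2.43 (SE 0.436, edgeR adjusted p = 0.00290), which turned to 1.88 (adjusted p = 0.723) with the series of sample codes as a term, resting on 0 and 3 reads in the female libraries. gHMG.13001750 (contig jcf7180004824008_779reversecomp_608_248, 11428 to 176871, 6 exons) had 0 reads in female, 3.49 CPM ± 0.262 in male and 1.58 CPM ± 0.438 in the variant (SD, n = 2 each). It was at least 56.7-fold higher in male and at least 25.6-fold higher in the variant than in female, and its log2 fold change of -1.17 between variant and male (SE 0.355, edgeR adjusted p = 0.0328) was not called by DESeq2 (adjusted p = 0.0735) nor without either variant library (0.0503 and 0.164). gSDR.13001840 and gHMG.13001750 share exons with other models, and counts of overlapping models are uncertain.

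A pair of models from this set was female-limited. gSDR.7.1 (77590 to 77706, 1 exon) and gSDR.8.1 (80083 to 80553, 2 exons) overlap no other model of the set and stood at 87.8 CPM ± 0.415 and 61.1 CPM ± 1.90 in female (SD, n = 2 each), with 2 reads and 1 read in male and 0 reads in the variant. Their exons sum to 117 and 127 bp, less than the read length of 150 bp, so reads of full length reach beyond the models. Whether these 2 models are pieces of 1 transcript was not tested. They lie on the contig Mp_4809344_Mp_4732415_Mp_4645105revcomp_Mp_4724600_Mp_4730479_Mp_4752867_Mp_4621808, which also carries male-limited models and whose joined name leaves open that it was assembled from separate pieces. Of the 41 tested models, 4 were higher and 26 lower in female than in male, 3 higher and 20 lower in the variant than in male, and 18 higher and 2 lower in the variant than in female. Adjusted over the list alone, the last count was 21 higher and 2 lower, and the others did not differ. Of 18 tested loci, 4 and 9, 1 and 5, and 5 and 2 were called in these comparisons. Of the 10 tested models with no overlap, 3 and 5, 1 and 2, and 3 and 2 were called. All 10 male-limited models of the set had reads in the variant, and 7 were called lower there than in male, with male levels 1.27 to 7.19 times those of the variant (median 2.88). Over all genes, 20 of 191 male-limited genes had 0 reads in the variant, and 2422 of 3000 male-biased genes (80.7%) were called lower there than in male. Neither count therefore sets the models of the set apart. gSDR.13001910, with 5 reads in female replicate 2, was above 0.1 CPM there and is not among the 10. Its male level was 1.03 times that of the variant. The 10 models fall into 4 loci. With all models of a locus summed, log2 fold changes of variant over male there were 0.12, -1.99, -1.36 and -1.42. The first and last were not called. Most of the first sum (297 CPM in female, 385 in male, 419 in the variant) came from gMSTRG.2.1, which is not male-limited (288, 253 and 374 CPM). The male-limited models of that locus, gMSTRG.3.1, gMSTRG.3.4, gHMG.13001750 and gMSTRG.3.10, were at -2.65, -1.32, -1.17 and -2.81, each called lower. With the series of sample codes as a term 2 of the models were called between variant and male, against 23 without it, and 13 between variant and female, against 20. Without female replicate 2 the latter count was 13 as well.

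**Figure D3:**
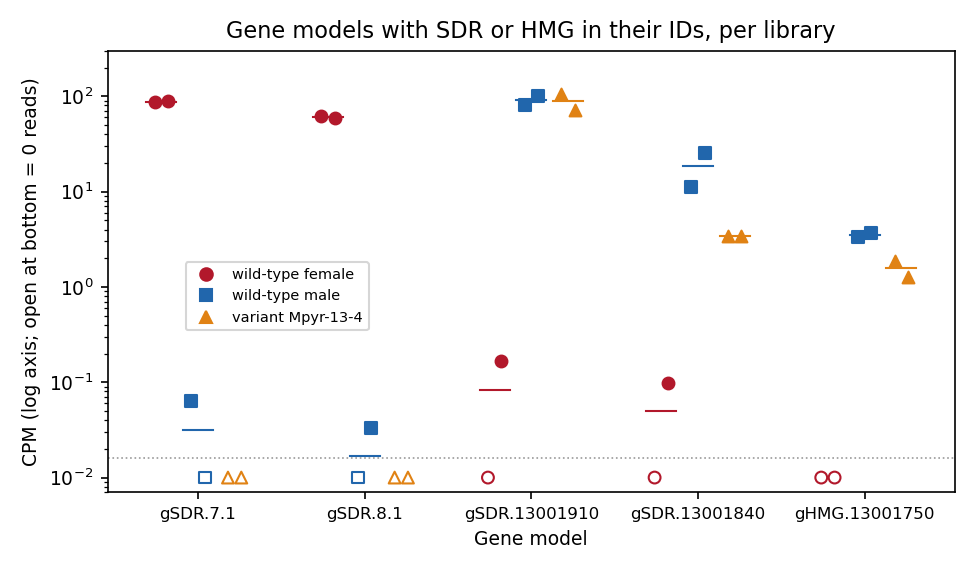
Points are the CPM of 5 gene models in each of the 6 libraries on a log axis, bars are group means, and open symbols at the bottom are libraries with 0 reads. gSDR.7.1 and gSDR.8.1 were read in female and had 0 reads in the variant, gSDR.13001910 was at a like level in male and the variant, and gSDR.13001840 and gHMG.13001750 were lower in the variant than in male, the former with replicates of male at different levels.

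Genes with a sex bias lay next to each other on contigs more often than random placement gave. Of 4197 neighbouring pairs of tested genes, 439 were both male-biased, against a mean of 149 in 10000 random placements, and 212 were both female-biased, against 116. Among sex-limited genes 32 pairs were both male-limited, against 0.617, and 19 both female-limited, against 2.26. Each one-sided p was 1e-04, the smallest these placements can give, and stayed there when adjusted over the 4 tests. Male-limited genes lay on 154 contigs, 24 of which held more than 1. Without the models carrying SDR, HMG or MSTRG, a setting added after the data were seen, the pairs were 28 for male-limited and 422 for male-biased genes. The annotation is fragmented, and 53.4% of genes are alone on their contig and have no neighbour.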

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

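Settings were planned apart from those on models carrying SDR, HMG or MSTRG. Over all of them, 661 of 722 values held, meaning that a tested value kept its direction and its side of the threshold, a count stayed within 1.5 times and any other value within the spread of replicates. Among counts and other summary values 209 held and 51 moved. Among fold changes of single genes, most of them named for their large changes, 452 held, 6 lost their call and 4 changed sign. The fold changes of named genes kept their calls, apart from gHMG.13001750 between variant and male (log2 -1.17), whose call was lost in 6 settings, and gSDR.13001840, which went from -2.43 to 1.88 with the series of sample codes as a term. gSDR.13001910, not called between variant and male (-0.05), was at 4.97 with that term and at -0.34 to 0.20 with a library left out, uncalled in each. Scaling by DESeq2's size factors, both other filters, DESeq2 itself and the authors' deposited tables left every count within 1.5 times, and the other scaling moved the split of higher against lower calls by less than 10 percentage points.

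The replicate numbers were not taken to pair the samples. Deviations of same-numbered libraries correlated at -0.0144 for female with male, 0.0158 for female with variant and -0.446 for male with variant. With the replicate number as a block, calls were 7938 for female against male, 6763 for variant against male and 1175 instead of 1953 for variant against female. Other counts under the block stayed within 1.5 times, and the smaller count comes with fewer residual degrees of freedom.

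With the series of sample codes as a term, calls of variant against male fell to 1847 (1845 with 2-fold) and of variant against female to 464 (462). SDR, HMG and MSTRG models called were 2 and 13, female-biased and male-biased genes toward female 1128 and 524, and variant-specific genes 62 and 39. The term leaves fewer degrees of freedom and rests on the female libraries alone for its size.

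Leaving out each library in turn, with a lone library taken to vary like the other groups, gave 5896 to 9681 calls for female against male, 441 to 3322 for variant against female (439 to 1627 with 2-fold), 13 to 23 SDR, HMG and MSTRG models for variant against female, 101 to 392 and 55 to 383 variant-specific genes higher and lower, and a position of 0.836 to 0.905 on male-biased genes. A fit of only variant and female gave 3326 calls. The cause of the higher count without male libraries was not tested. The chi-square between replicates was highest in male.

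Without a fold threshold for bias 3489 female-biased genes were called toward female and the position on male-biased genes was 0.830. With a 4-fold threshold these counts were 1000 and 1406 and the positions 0.958 and 0.950. With bias taken from replicate 1 of each sex and position from the other, the positions on female-biased and male-biased genes were 0.888 and 0.920, and with the replicates exchanged 0.803 and 0.859. At 5 CPM there were 137 female-limited genes (85 on in the variant) and 59 male-limited genes (31 on), and with 0 reads in the other sex 158 (91) and 77 (32), since these thresholds admit fewer genes. The correlation of fold changes over male was 0.874 among genes with a mean log2 CPM of at least 3. Tests of the lists of product names with camera and fry were not run, because the files do not pair IDs with names. Depth limited the reading of low genes most in variant replicate 1, where 3 reads are 0.236 CPM.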

Other observations

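The tests below were chosen after the results had been seen, apart from the test of neighbouring genes 2 kb or more apart.

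On and off states over the 3 groups set male apart. The 247, 65, 47 and 43 genes below are the sex-limited genes already given, on or off in the variant. With the thresholds of 1 and 0.1 CPM, 247 genes were off in male and on in female and the variant, 65 were off in female and on in the other groups, and 4 were off in the variant and on in both sexes. In the opposite sense 47 genes were on in female alone, 43 in male alone and 1 in the variant alone. With 0 reads in both libraries of a group and at least 5 CPM in each of the other 4 libraries, these losses numbered 19 in male, 11 in female and 1 in the variant, g44297. A further 20 genes had at least 5 CPM in both female libraries, at most 0.1 CPM in both male libraries and 0 reads in the variant. Together they summed to 647 CPM ± 5.37 (SD, n = 2) in female. gSDR.7.1 and gSDR.8.1 were among them.

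The variant lay near female at most sex-biased genes. Female RNA mixed into the variant libraries would carry every abundant female transcript with it, but 20 of 137 female-limited genes at 5 CPM or more had 0 reads in the variant, and mislabelled libraries of the female strain would lack male-limited genes, but 65 of these were at 1 CPM or more in both variant libraries. An effect of the series of sample codes would draw female replicate 2 toward the male libraries of its series, and that library was nearer than female replicate 1 to both male libraries (226 against 235 and 249 against 257), though also to both variant libraries of the other series (136 against 138 and 130 against 132). Its distance to the other female library was 0.186 times its smallest distance to a male library, which leaves room for a part of the pattern and not the whole. A biological difference of the line stays open and untested, since the design cannot part its derivation, the colchicine treatment and strain differences from each other.

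Of the 10 male-limited models among those carrying SDR, HMG or MSTRG, 7 were called lower in the variant than in male. So were 2422 of all 3000 male-biased genes (80.7%), so the fall is not particular to these models. The 10 fall into 4 loci, so neither the count of 7 nor their Cochran's Q below rests on 10 independent units. Male RNA diluted in the variant libraries would lower all by a common factor, but the log2 fold changes of the 10, 9 of which overlap other models, ranged from -2.81 to -0.34 (Cochran's Q of 41.8 on 9 degrees of freedom). Those of the 4 models with no overlap that were at least 4-fold lower in female than in male ranged from -2.62 to -0.05 (Q of 31.8 on 3 degrees of freedom), the highest of them gSDR.13001910. Reads dropped where models overlap were looked at by comparing models with and without overlap. Of 5 models with no overlap that were lower in female than in male, 1 was also lower in the variant, against 18 of 21 models with overlap. The uncalled ones were gSDR.5.8 (log2 -1.42, 1.83 CPM in male), gMSTRG.3.15 (-1.29, 0.764 CPM), gSDR.13001910 (-0.05) and gSDR.4.1 (0.40). Low counts limit calls at the first of these, and models with overlap share exons, so these counts cannot decide whether dropped reads play a part. The same counting was applied to every library, so dropped reads would lower a model in the variant against male only if its reads lay differently along the exons there. Positions of reads are not in the counts, so this was not tested. A biological difference in the models that overlap stays untested as well.

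Neighbouring genes shared a sex bias. Gene models split in the annotation could place pieces of a gene side by side, and 57.9% of the male-biased pairs were on the same strand against 31.4% of other pairs. Pairs on opposite strands, which cannot be pieces of the same gene, were still in excess, with 184 male-biased pairs against 98.1 at random and 97 female-biased pairs against 76.5 (larger one-sided permutation p = 0.009). Reads spilling into the next model would leave distant pairs at the random level, but pairs 2 kb or more apart numbered 168 against 62.0 and 116 against 48.3 (one-sided permutation p = 1e-04 for both, the smallest the placements can give). Neither explanation alone accounts for the whole excess, and each may account for part of it. Pairs that were both on opposite strands and 2 kb or more apart were not counted. Both explanations together are therefore not excluded, and no biological explanation was tested.

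Among 40 genes with at least 20 CPM in both male libraries and at most 20 reads in both female libraries together, female replicate 2 held 181 reads and female replicate 1 held 55, a share of 76.7% for replicate 2 against 62.0% by depth. These levels were 0.221% and 0.110% of those in male. Among 26 genes chosen in the same way from the variant libraries, 21 of them the same genes, female replicate 2 held 115 reads and female replicate 1 held 24, a share of 82.7%. These shares compare single libraries and were not tested against the spread between bulks.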
